A study of Synechocystis sp. PCC 6803 with 15 samples.

How the data were processed

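RNA sequencing libraries of the unicellular cyanobacterium Synechocystis were compared. Per the labels' protocols, cultures grew in BG11 medium for 5 days with or without erythromycin, a macrolide antibiotic that binds the bacterial ribosome, and RNA was extracted with TRIzol. Strand-specific total RNA libraries were made after ribosomal RNA removal. The 15 libraries were placed in 5 groups of 3 from their titles. The groups are Synechocystis grown alone without erythromycin, Synechocystis grown alone with erythromycin, the co-culture with the filamentous fungus Penicillium without erythromycin, and 2 kinds of co-culture sample with erythromycin that the titles prefix with LR and SS. The labels do not spell out LR or SS, and these prefixes are used as names only. Every co-culture sample with erythromycin carries a prefix and no co-culture sample without it does, so erythromycin is confounded with whatever the prefixes mark. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

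The authors quantified each library with Salmon, per the submitters' processing notes, which also name FastQC and DESeq2. The only genome build in those notes is mm10, a mouse build. The transcript set, the library type setting and the tool versions are not given in the sources used here. Each deposited table lists the same 3514 rows with length, effective length, TPM and estimated counts, per the file headers. All 3514 lengths (90 to 12600 nt, median 793.5 nt) are multiples of 3, so they are coding lengths. Estimated counts, as the authors deposited them, are not normalized. They were rounded to whole numbers before testing. Between 2.19% and 5.24% of a library's values were not whole within 0.0005 in Synechocystis grown alone, and between 19.81% and 57.0% in co-culture. The authors' TPM values, scaled by Salmon to one total per library with the effective lengths, were used only for rank correlations between libraries and for percentiles.

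Quantification differed between groups. In all 6 libraries of Synechocystis grown alone the length minus the effective length reached exactly 250.0 nt, the same value in each. In the 9 co-culture libraries it took a value of its own per library, from 144.3 to 167.1 nt. The share of values that were not whole was also lower in every library grown alone than in any co-culture library. Penicillium and these differences in quantification are therefore confounded. Offsets from effective lengths correct for the lengths used, and not for any other difference in read handling.

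Row identifiers begin with BAA (3143 rows), BAB (2 rows) or BAD (369 rows), and the files do not pair them with gene names. None of them (0 of 3514) matched an entry of the RefSeq gene table of assembly ASM28445v1 that was used. The 24 gene lists fixed before the data were examined (376 members, given as locus tags, among them pilins, pilus assembly, photosystems, phycobilisome, ribosomal proteins, carbon, nitrogen, phosphate and iron uptake, chaperones, sigma factors and drug efflux) could therefore not be applied, and 0 of their tags occurred in the files. No gene list test was run and no gene is named here. A row below is 1 coding sequence under its deposited identifier.

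Total estimated counts ranged from 19879268 to 24473219 in the co-culture without erythromycin, from 25776579 to 29597847 in LR, from 8486394 to 13776965 in SS, from 3127659 to 19777251 in Synechocystis alone without erythromycin and from 137655 to 297528 in Synechocystis alone with erythromycin. Intervals and floors cover counting error only, since the files hold no molecular identifiers. No 2 libraries of a group held identical values, and the chi-square per degree of freedom between replicates was 3.21 or more for all 15 pairs, so each library was counted as 1 sample.

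Differences were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM normalization, filterByExpr (3510 rows kept) and 1 fit over all 5 groups without covariates. A row was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 7 pairwise comparisons and the 2 interactions, the rule for naming rows and most alternatives were fixed before the data were examined. That rule ranks rows by fitted fold change among those past the test, with an average log2 CPM of at least 4 and with all 3 libraries of one group above all 3 of the other. The average was taken over all 15 libraries. A row could thus pass it through groups outside its comparison, among them the untreated cells grown alone. The rule would name up to 8 of each direction in some comparisons and up to 5 in the others. Only the first 2 of each direction are given, a limit set after the data were seen because the identifiers carry no names, and the rest are summarised as counts. The rows ranked by the rule for the 2 interactions were computed, seen and then left out, and the interactions are given as counts. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. Where all libraries of a group were at 0, a fold is given as a lower bound against a floor of 3 counts over the group. These bounds use library totals scaled by the TMM factors and hold under that scaling only. They allow for no counting error in the higher group. A row listed at 0 in estimated counts may have lost its reads to a near-identical row, which was not checked because sequences were not used here.

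The test was tried on simulated data with real library sizes, 3510 rows and 200 rows changed in each pairwise comparison, in 2 versions. Both groups compared took the real means of 1 of them, apart from the changed rows, which rose and fell equally often. In comparisons with untreated cells grown alone these means came from the other group. The near-even profile of the untreated cells was thus left out there, and normalization with most rows changed was not tried. The first version simulated only the groups compared and left the other groups at their real counts. In it 11.9% of the calls were false for treated against untreated cells grown alone, 11.2% for SS and 1.6% for LR against the untreated co-culture, 11.3% for SS and 6.5% for LR against treated cells grown alone, 9.3% for LR against SS and 1.1% for the untreated co-culture against untreated cells grown alone. The second version, adopted after these values were seen, simulated all 15 libraries with one common spread, and 6.9%, 5.9%, 4.9%, 1.5%, 4.5%, 5.3% and 3.5% of the calls were false in the same order. The 2 versions differ in whether the other groups were simulated, and with that in whether all groups share one spread. The cause of the differing shares was therefore not isolated. Where groups do not share one spread, as the real groups may not, a pooled spread can put the share of false calls above the nominal 5%. The counts of changed rows may thus hold more false calls than the threshold states. Of rows changed 4-fold, the first and second versions recovered 99% and 100% for LR against SS, 100% in both for LR and 99% in both for SS against the untreated co-culture, 97% and 98% for the untreated co-culture against untreated cells grown alone, 83% and 89% for treated against untreated cells grown alone, and 85% and 92% for LR and 84% and 90% for SS against treated cells grown alone. Of rows changed 2-fold they recovered, in that order, 97% and 96%, 84% and 94%, 91% and 94%, 80% and 95%, 43% and 46%, 44% and 55%, and 49% and 44%.

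Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom (limma 3.58.1), no filter, a mean of at least 50 counts, offsets from effective lengths, only the groups compared, a replicate block and leaving out each library. Thinning all libraries to 137655 counts, keeping only rows of at least 600 nt, and fits without the libraries grown alone were added after the data were seen. Leaving out rows of structural RNA, planned beforehand, was not run because no row could be matched to one. The grouping of rows by the BAD prefix was also chosen after the data were seen. Same-numbered libraries did not deviate together in any of the 10 pairs of groups (correlations from -0.1 to 0.13), so numbers were not treated as pairs. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining values and the plots. No value column was left without a library.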

Results

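The data describe transcript levels of the cyanobacterium Synechocystis in 15 RNA sequencing libraries, 3 in each of 5 groups, over 3514 coding sequences (rows). The design crosses erythromycin, an inhibitor of bacterial translation, with co-culture with the fungus Penicillium. It adds a second kind of co-culture sample under erythromycin, so that LR and SS are compared with each other as well. The series sets Synechocystis in the biomass it forms with the fungus against erythromycin-treated Synechocystis without the fungus, with an interest in pilin genes. The rows carry protein identifiers that were not matched to gene names, so pilin genes are not reported here. Total estimated counts per library were 3127659, 13044710 and 19777251 in untreated cells grown alone and 147438, 137655 and 297528 in treated cells grown alone. They were 22908821, 19879268 and 24473219 in the co-culture without erythromycin, 29597847, 26407482 and 25776579 in LR, and 13776965, 8486394 and 8911081 in SS. Detection of small changes was therefore limited most in comparisons with treated cells grown alone.

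The 9 co-culture libraries and the 3 libraries of erythromycin-treated cells grown alone had steep expression profiles. Their 10 most abundant rows took between 30.96% and 43.04% of the counts. In the co-culture without erythromycin the single most abundant row, BAA17449, took 10.43% to 12.24%. The 3 libraries of untreated cells grown alone differed from all of these. Their 10 most abundant rows took 3.55% to 3.76%, and the 75th percentile of reads per 1000 nt was 1.37 to 1.47 times the 25th, against 7.07 to 9.38 times in the other 12 libraries. Row identifiers that begin with BAD took 13.38% to 14.67% of the counts of the untreated libraries, against 0.93% to 4.8% in the others, for 8.55% of the total row length.

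**Figure D1:**
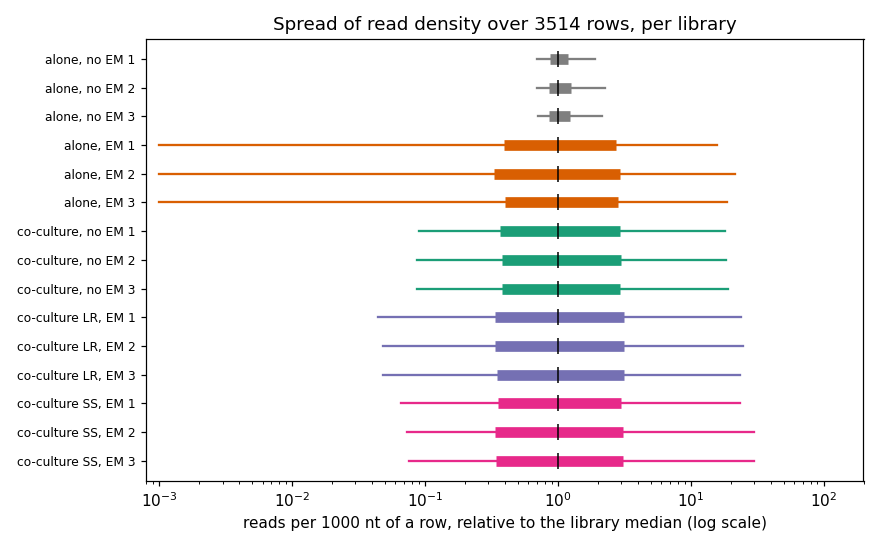
Reads per 1000 nt of each row relative to the library's median (log axis) for the 15 libraries. Thick bars span the 25th to 75th percentiles, thin lines the 5th to 95th (a 5th percentile of 0 is drawn at the left end), and ticks mark the median. The 3 untreated libraries grown alone have ratios of 1.37 to 1.47 between the 75th and 25th percentiles, and the other 12 have 7.07 to 9.38.

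Spearman correlations of TPM across rows, which are not independent replicates, were 0.99 to 1.0 within the co-culture without erythromycin and within LR. They were 0.95 to 0.99 within SS, 0.97 to 1.0 within untreated cells grown alone and 0.76 to 0.85 within the shallow libraries of treated cells grown alone. The treated cells grown alone reached 0.73 to 0.8 with SS, 0.68 to 0.76 with LR and 0.59 to 0.69 with the co-culture without erythromycin, so their range with SS overlapped that among themselves. Correlations between LR and SS libraries were 0.92 to 0.94. The co-culture without erythromycin reached 0.68 to 0.69 with LR and 0.69 to 0.71 with SS. Untreated cells grown alone lay between -0.09 and 0.24 with every library of the other groups.

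**Figure D2:**
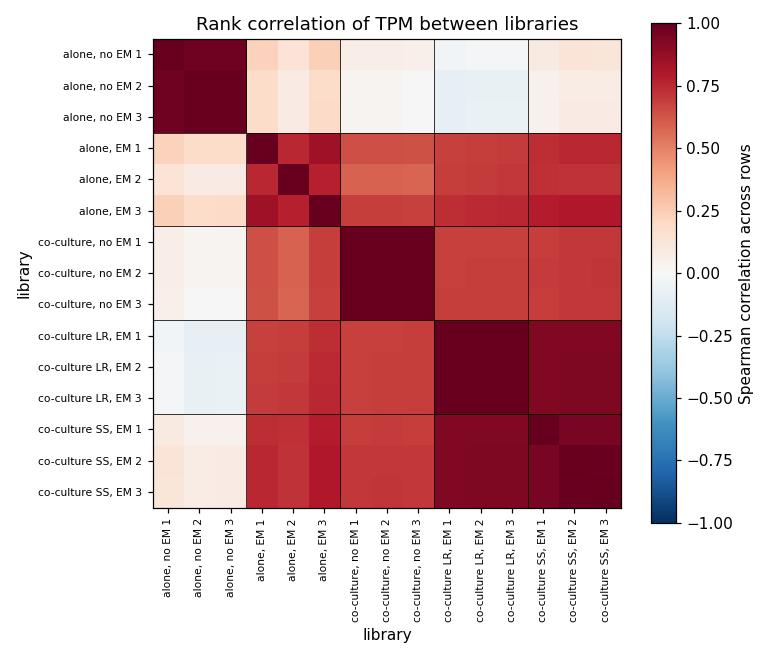
Spearman correlation of TPM across 3514 rows between all pairs of the 15 libraries, on a color scale from -1 to 1. Rows and columns are libraries, ordered by group. LR and SS form a block of 0.92 to 0.94 with each other, and the 3 untreated libraries grown alone stay between -0.09 and 0.24 with all others.

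The first comparison set co-culture samples with erythromycin against those without. All of its libraries come from co-culture, with an effective length estimated per library. The samples with erythromycin also carry the prefix LR or SS and those without carry none, so erythromycin and whatever the prefixes mark cannot be told apart here. In LR, 1419 of 3510 rows were higher and 1380 lower than in the co-culture without erythromycin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 967 and 950 of them differed at least 2-fold. By fitted fold change 155 rows were at least 16-fold lower and 58 at least 16-fold higher. The consecutively numbered rows BAA17437 (2256 nt) and BAA17438 (2196 nt) fell furthest among the rows past the naming rule. BAA17437 went from 70350 ± 8790 CPM without erythromycin to 126.6 ± 22.6 CPM in LR (SD, n = 3), a log2 fold change of -9.12 (SE 0.763, adjusted p = 1.99e-08). BAA17438 went from 72880 ± 8040 to 166.1 ± 21.8 CPM, a log2 fold change of -8.78 (SE 0.637, adjusted p = 3.78e-09). BAA18046 and BAA18044 were at 0 counts in all 3 co-culture libraries without erythromycin. They reached 59.02 ± 24.7 and 5.091 ± 0.786 CPM in LR, at least 1010-fold and at least 89.3-fold higher than the floor of 3 counts over the group. Such bounds compare the counts summed over each group, so they can differ from ratios of the mean CPM. Reads shared with a near-identical row cannot be excluded for such rows. In treated cells grown alone BAA17437, BAA17438, BAA18046 and BAA18044 were at 855.4 ± 479, 683.5 ± 356, 70.66 ± 66.7 and 47.62 ± 49.9 CPM. In untreated cells grown alone they were at 372.7, 363.4, 79.77 and 187.5 CPM. By these means the co-culture without erythromycin stood apart from all other groups in these rows. The rows were ranked by their change from that group, so this was partly built in. It also stayed open whether the reads of untreated cells grown alone came from RNA. Counts in the libraries of treated cells grown alone were 0, 11 and 45 for BAA18046 and 19, 6 and 0 for BAA18044. All 3 libraries of one group lay above all 3 of the other for 3036 of 3510 rows, where chance gives 10%. At the depth of the shallowest library 1367 rows were called, and BAA18044, then at 2 counts over the LR libraries against 0, no longer passed the test (adjusted p = 0.279). DESeq2 size factors moved the median of all rows from 0.03 to -0.09 and the split to 1314 higher and 1470 lower. The 365 rows with BAD identifiers, a grouping chosen after the data were seen, had 97 higher and 166 lower in LR (median -0.33, camera, adjusted p = 0.0153 with a preset correlation of 0.01 and adjusted p = 0.55 with an estimated correlation). The split of all rows also turned under the DESeq2 Wald test (1383 and 1555), after thinning (624 and 743) and among rows of at least 600 nt (880 and 947).

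In SS the same comparison gave 1412 rows higher and 1328 lower, with 937 and 886 at least 2-fold and 71 and 114 at least 16-fold. LR and SS were compared with the same co-culture libraries without erythromycin, so a row extreme in those ranks high in both, and the rankings are not independent. Among rows past the naming rule, BAA17438 and BAA17437 fell furthest here too, with log2 fold changes of -8.46 (SE 0.63, adjusted p = 6.06e-09) and -7.88 (SE 0.725, adjusted p = 7.21e-08). Their SS levels were 207.3 ± 55.5 and 298.0 ± 182.0 CPM (SD, n = 3), and without SS replicate 1 the value of BAA17437 was -8.51. BAA18046 and BAA18044 were at 70.31 ± 25.7 and 17.75 ± 10.6 CPM, at least 1090-fold and at least 255-fold above the floor. Leaving out the 6 libraries grown alone gave 2769 changed rows for LR and 2727 for SS, against 2799 and 2740 with them. Of the rows with BAD identifiers 147 were higher and 114 lower in SS (median 0.21, camera, adjusted p = 0.41 and adjusted p = 0.791). Thinned to the shallowest library, the SS comparison called 1241 rows. The split turned to 1355 higher and 1390 lower with DESeq2 size factors, to 1434 and 1461 under the DESeq2 Wald test and to 598 and 643 after thinning.

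Next, the 2 kinds of erythromycin-treated co-culture sample were set against each other. LR and SS differed in 1849 rows, 911 higher and 938 lower in LR, but the differences were smaller than those between either group and the untreated co-culture. Their median absolute log2 fold change was 0.51, against 1.14 and 1.06, and 0 rows were at least 16-fold higher and 6 at least 16-fold lower in LR. Rows at least 2-fold apart were mostly lower in LR, with 476 lower and 221 higher. Among rows past the naming rule, at any fold, 858 were higher and 758 lower. The 2-fold split was not taken under other settings. With DESeq2 size factors, which put the median of all rows at -0.08 where TMM put it at -0.02, 802 rows were higher and 1030 lower. The split turned to 914 higher and 871 lower under limma-voom, to 844 and 766 without the untreated libraries grown alone in the fit, and to 1123 and 1054 without SS replicate 1. Rows with BAD identifiers moved mainly downward in LR, with 200 of 365 lower, 17 higher and 148 not past the test. Their median log2 fold change was -0.81, against 0.05 for the other rows (camera, adjusted p = 3.46e-14 with a preset correlation of 0.01 and adjusted p = 0.146 with an estimated correlation). The largest increases in LR among rows past the test were BAA17298, at 48.69 ± 5.96 CPM against 5.909 ± 1.11 in SS (log2 fold change 3.08, SE 0.239, adjusted p = 3.43e-07), and BAD02100, at 151.8 ± 35.1 against 25.08 ± 1.66 CPM (log2 fold change 2.59, SE 0.156, adjusted p = 2.74e-08). BAA17928 was at 41.64 ± 3.12 CPM in LR and 2444 ± 1960 CPM in SS (log2 fold change -5.87, SE 0.751, adjusted p = 1.96e-05). BAA18407 ranked next with -5.2 (SE 1.13, adjusted p = 0.00134), but this value rests on SS replicate 1, without which it was -0.51 (adjusted p = 0.228), and limma-voom gave -3.26 (adjusted p = 0.0503). SS replicate 1 lay at least 4-fold above both other SS libraries in 22 rows and below both in 67, and without it the comparison called 2177 rows. Thinned to the depth of the shallowest library, LR and SS differed in 235 rows, and BAA17298, then at 8 counts over the LR libraries against 0 over the SS libraries, no longer passed the test (adjusted p = 0.0809).

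The comparison that the series describes sets co-culture under erythromycin against Synechocystis grown alone under erythromycin. LR had 1090 rows higher and 854 lower than treated cells grown alone, with 816 and 666 at least 2-fold. SS had 896 higher and 702 lower, with 684 and 489 at least 2-fold. The SS count fell to 991 rows when only these 2 groups were fitted, and thinning gave 1112 rows for LR (506 higher and 606 lower) and 812 for SS. DESeq2 size factors moved the median of all rows in LR from 0.11 to -0.01, with 991 rows higher and 951 lower. The LR split turned to 1008 higher and 1106 lower under the DESeq2 Wald test and to 869 and 910 when only these groups were fitted. Of 365 rows with BAD identifiers, 158 were lower and 10 higher in LR, and 96 were lower and 44 higher in SS. Their medians were -0.94 and -0.29, against 0.22 and 0.15 for the other rows. The adjusted p from camera was 4.38e-11 and 0.000561 with the preset correlation, and adjusted p = 0.146 and 0.406 with an estimated correlation. BAD02086 was at 5.239 ± 0.53 CPM in LR and 550.5 ± 155.0 CPM in treated cells grown alone (SD, n = 3), a log2 fold change of -6.69 (SE 0.551, adjusted p = 1.53e-07). BAD02077 ranked next with -6.54 (SE 1.28, adjusted p = 0.000472), from 8 counts over the LR libraries and 11 over the treated cells. It lay between -5.89 without LR replicate 1 and -7.91 without LR replicate 3. It was -5.96 and -7.25 without replicates 1 and 3 of the treated cells, and -8.9 with effective length offsets. BAD02077 was at 0.1839 ± 0.212 CPM in LR and 19.66 ± 12.9 CPM in treated cells grown alone. Its highest level, 95.49 ± 2.2 CPM, was in untreated cells grown alone, which also entered the average CPM of the naming rule. In SS, BAD02042 ranked first of the lower rows under the naming rule, from 220.1 ± 255.0 to 2.34 ± 0.5 CPM (log2 fold change -6.32, SE 0.725, adjusted p = 5.19e-06), with -4.86 without replicate 2 and -7.0 without replicate 3 of the treated cells. BAD02079 was at 10.29 ± 2.7 CPM in SS and 574.0 ± 398.0 CPM in treated cells grown alone, a log2 fold change of -5.76 (SE 0.426, adjusted p = 6.81e-08), and -5.09 without replicate 2 of the treated cells. Among rows at 0 counts in treated cells grown alone, BAA10334 and BAA10085 were at least 8.47-fold and at least 8.11-fold higher in LR, and BAA17571 and BAA10164 at least 13.3-fold and at least 8.36-fold higher in SS. Between 191 and 516 rows were at 0 in each of these shallow libraries, and 3 counts over the group correspond to 4.49 CPM. Replicate 2 of the treated cells lay at least 4-fold above both others in 54 rows and below both in 136. Effective lengths were preset in cells grown alone and estimated per library in co-culture. With effective length offsets 2024 rows were called for LR and 1690 for SS, and the log2 fold changes of BAD02086 and BAD02079 were -6.78 and -5.63. Any other difference in read handling cannot be told apart from Penicillium here.

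Both comparisons named next used the untreated cells grown alone, whose reads were spread almost evenly over rows. It stayed open whether these reads came from RNA, so the counts and folds below need not reflect expression. Treated cells grown alone had 1099 rows higher and 1501 lower than the libraries labelled untreated, with 922 and 1300 at least 2-fold. The co-culture without erythromycin had 1398 higher and 1645 lower, with 1073 and 1275 at least 2-fold. BAA10743, at 0 counts in the untreated libraries, was at least 5580-fold higher in treated cells grown alone (from 81 counts over the group). It was at least 895-fold higher in the co-culture. BAA10464 was at 65290 ± 15900 CPM in treated cells grown alone against 48.31 ± 19.3 CPM (log2 fold change 10.4, SE 0.486, adjusted p = 5.12e-11). BAA17449 was at 144400 ± 19000 CPM in the co-culture without erythromycin against 151.0 ± 56.7 CPM (log2 fold change 9.9, SE 0.472, adjusted p = 1.92e-11). BAD02007 was at 286.5 ± 24.9 CPM in the untreated libraries and at 0 counts in both other groups, as it was in LR and SS. It was at least 65.5-fold lower in treated cells grown alone and at least 5120-fold lower in the co-culture. These bounds, too, compare counts summed over each group. They rest on the TMM factors given below, which were far higher in the untreated libraries than in the others. BAA18372 was at least 54.2-fold lower in treated cells grown alone, and BAA18044 at least 3430-fold lower in the co-culture. Rows with BAD identifiers were lower in 218 and 288 of 365 cases and higher in 64 and 41, with medians of -1.57 and -2.15 (camera, adjusted p = 3.58e-05 and 4.25e-13 with the preset correlation, and adjusted p = 0.406 and 0.164 with an estimated correlation). TMM factors were 3.81 to 3.867 in the untreated libraries and 0.462 to 1.294 in the others. The median of all rows was -0.42 and -0.21 under TMM and -0.52 and -0.31 under DESeq2 size factors.

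**Figure D3:**
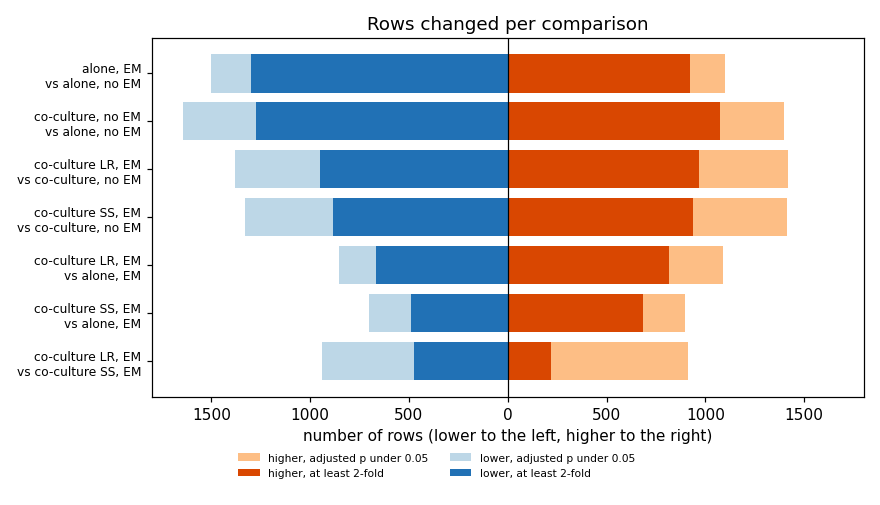
Number of rows past an adjusted p of 0.05 in the 7 pairwise comparisons, higher to the right and lower to the left of 0 (linear axis). Light bars count all changed rows and dark bars those at least 2-fold apart. LR against SS has 911 rows higher and 938 lower, of which 221 and 476 are at least 2-fold apart.

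Whether the differences between samples with and without erythromycin were alike with and without Penicillium was asked across rows, between comparisons that share no library. The log2 fold changes of treated against untreated cells grown alone correlated with those of LR against the untreated co-culture at Pearson 0.25 and Spearman 0.24, and with those of SS at Pearson 0.23 and Spearman 0.24. In both cases 56.8% of the 3510 rows had the same sign. The interaction was past the threshold for 2478 rows with LR (1350 above and 1128 below 0) and for 2516 rows with SS (1385 and 1131). Rows with BAD identifiers were above 0 in 161 cases and below in 74 with LR (median 1.05) and in 206 and 49 with SS (median 1.88). The camera test gave adjusted p = 0.124 and 4.48e-05 with the preset correlation, and adjusted p = 0.712 and 0.406 with an estimated correlation. Thinned to the depth of the shallowest library, the split of all rows turned to 497 above and 858 below 0 for LR and to 479 and 822 for SS, and among rows of at least 600 nt it was 792 and 799 for LR. Both interactions, and both correlations, contain the untreated libraries grown alone, whose read density was nearly even over rows.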

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

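All tests in this part on the untreated libraries and both counts of other splits were chosen after the results were seen, while the interactions were planned.

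The difference between libraries labelled with and without erythromycin was itself different between cells grown alone and co-culture in 2478 rows for LR and 2516 rows for SS, by the interaction term of the edgeR fit. This does not establish a different response to erythromycin, because both interactions rest on the untreated libraries grown alone and on co-culture samples whose prefixes are not explained. Of 100 drawn splits that regroup libraries within each pair of groups, 1 gave as many rows for LR (2478 for the real split, 1371 for the highest other). For SS 2 of 100 did. The other one, with 2680 rows against 2516, kept the co-culture groups and exchanged the erythromycin labels of the cells grown alone, so it follows the groups. That exchange was not among the splits drawn for LR. The remaining splits mix libraries of groups that differ strongly, so lower counts were to be expected from the design, and these splits do not decide whether chance can be excluded.

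The read density of the untreated libraries grown alone was nearly even over rows. Depth is argued against, since co-culture libraries thinned to the totals of the untreated libraries kept a ratio of 7.76 or more between the 75th and 25th percentiles. The preset fragment length is argued against too, since treated cells grown alone were quantified with it and had a ratio of 7.07 or more. Reads from genomic DNA in place of RNA stay open. The ratio of at most 1.47 is the pattern itself and gives no support for them. Within each of 3 runs of consecutively numbered BAD rows a ratio under 2 was asked for. It was at most 1.56 and 1.46 in 2 runs, and 1.93 to 2.12 in the run of 63 rows. Counts followed row length in these libraries (Spearman 0.88 to 0.91, against 0.2 to 0.35 in the others), which restates the even density. An even profile of untreated cells without the fungus also stays open, as untested, because no other group shares that condition.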

How the results depend on the processing

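The thinning to 137655 counts, the restriction to rows of at least 600 nt and the fits without libraries grown alone were chosen after the data were seen. Every count of changed rows stayed within 1.5 times its main value under DESeq2 size factors, the DESeq2 Wald test, limma-voom, no filter, the stricter filter and effective length offsets. Fitting only the groups compared did so too, except for SS against treated cells grown alone (991 for 1598, the cause was not tested). No filter and the stricter filter left 3514 and 3505 rows to test in place of 3510, so these settings could hardly move a count. Thinning called 1367 rows for LR and 1241 for SS against the untreated co-culture, 1112 and 812 against treated cells grown alone, 235 between LR and SS, and 1355 and 1301 for the interactions, so those counts are limited by depth. Thinning also moved the split of the interactions, from 1350 above and 1128 below 0 to 497 and 858 for LR and from 1385 and 1131 to 479 and 822 for SS, and the cause was not tested. The 2 remaining counts stayed within 1.5 times. Keeping only rows of at least 600 nt left 2243 rows to test in place of 3510, and so called 1606 and 1920 rows for treated cells alone and the untreated co-culture against untreated cells alone, 1827 and 1790 for LR and SS against the untreated co-culture, 1319 (within 1.5 times) and 1057 against treated cells alone, 1229 between LR and SS, and 1591 (792 above and 799 below 0) and 1618 for the interactions. Fits without the untreated libraries grown alone, or without any library grown alone, moved no count by over 1.5 times. Leaving out 1 library gave 2257 to 2518 rows for treated against untreated cells grown alone, 2932 to 2964 for the co-culture against untreated cells alone, 2678 to 2705 and 2603 to 2819 for LR and SS against the untreated co-culture, 1633 to 1913 and 1298 to 1668 against treated cells alone, 1562 to 2177 between LR and SS, and 2248 to 2478 and 2283 to 2570 for the interactions. DESeq2 size factors moved the median of all rows furthest in LR, from 0.03 to -0.09 against the untreated co-culture and from 0.11 to -0.01 against treated cells alone. The replicate block gave 2586, 3013, 2762, 2679, 1912, 1562, 1763, 2442 and 2465 rows in the order of the comparisons in the plot of changed rows followed by the interactions, and changed no count by over 1.5 times. The share of higher calls changed sides of an even split under some settings for LR and SS against the untreated co-culture. It did so too for LR against treated cells alone, for LR against SS and for both interactions. No direction is therefore read from the counts of all changed rows in any of these. Libraries matched their own number best in 19 of 60 cases, so the numbers pair nothing. The correlations of erythromycin effects stayed at 0.25 and 0.23 under the 4 alternatives run for them. These were DESeq2 size factors, no filter, the stricter filter and the replicate block. Such settings rescale libraries, change few rows or leave group means nearly alone, so they could hardly move a correlation. Thinning, the restriction by row length and leaving out libraries were not run for the correlations. Of 464 alternative values of named rows, 460 kept direction and threshold, 4 kept direction only and 0 reversed. These rows were picked as extreme in the same libraries, so this was likely from the start. Fitted sizes against groups at 0 counts did move. Under limma-voom BAA10334 in LR against treated cells alone went from 12.34 to 3.98. BAD02007 in treated against untreated cells alone went from -15.25 to -6.87. Leaving out structural RNA rows was not run, as no row was known to be one, and gene list tests were not run.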

Other observations

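Of the tests in this part, the permutation test of similarity to treated cells grown alone, the one of TPM percentiles, the counts of other splits and all values on BAD identifiers were chosen after the results were seen.

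Rows with consecutive identifier numbers tended to change together (their places in the genome were not used here). In LR against the untreated co-culture, 71.4% of 2254 neighbouring pairs of changed rows moved in one direction, and in SS 71.5% of 2163 pairs did. In 10000 shuffles of the directions the highest shares were 53.6% and 54.2% (permutation p = 0.0001, the smallest these shuffles can give). The share was 79.3% of 1068 pairs between LR and SS, and over the 7 pairwise comparisons and 2 interactions it ranged from 63.0% to 80.9%. Transcription of neighbouring rows as a unit is a candidate explanation that these shares allow, and the pair BAA17437 and BAA17438 is an example of such neighbours. The shuffles cannot tell it from shifts of longer stretches of consecutive rows, such as the BAD rows that moved mainly downward in LR against SS.

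Among BAD identifiers, 3 runs of consecutive numbers held 150, 132 and 63 rows. In the untreated libraries grown alone their median read density was 1.01 ± 0.06, 1.92 ± 0.14 and 2.44 ± 0.03 times that of the other rows (SD, n = 3). In LR it was 0.22 ± 0.02, 0.26 ± 0.04 and 0.2 ± 0.02, and in SS 0.35 ± 0.0, 0.44 ± 0.04 and 0.32 ± 0.02. In the co-culture without erythromycin it was 0.28 ± 0.02, 0.39 ± 0.02 and 0.44 ± 0.01, and in treated cells grown alone 0.42 ± 0.15, 0.68 ± 0.13 and 0.97 ± 0.49.

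Treated cells grown alone ranked rows more like the treated than like the untreated co-culture. Their mean Spearman correlation was 0.714 ± 0.007 with LR, 0.758 ± 0.006 with SS and 0.638 ± 0.004 with the co-culture without erythromycin (SD, n = 3). The difference between treated and untreated co-culture was the largest of all 84 ways to pick 3 of the 9 libraries (exact one-sided permutation p = 0.0119, the smallest possible). This p adds nothing to the means, because the libraries of each group lay together, so it follows from the order of the 3 groups. Depth is argued against, since the difference was 0.072 after all libraries were thinned to one total, with means of 0.633 ± 0.005 for LR, 0.67 ± 0.004 for SS and 0.579 ± 0.01 for the untreated co-culture. A response to erythromycin shared with and without the fungus stays open, and other differences between these co-cultures, such as library handling or whatever the LR and SS prefixes mark, stay open too, as untested.

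Single libraries stood apart in SS and in treated cells grown alone. In the latter, replicates 1, 2 and 3 were at least 4-fold above both others in 26, 54 and 23 rows and below both in 45, 136 and 53, at far lower depth. SS replicate 1 was at least 4-fold above both in 22 rows and below both in 67, against 1 and 5 rows for replicate 2 and 4 and 5 for replicate 3. DNA reads spread over rows are argued against, because the 5th percentile of TPM rose by only 0.063 of the rise of the median (0.93 against 0.62 and 0.64, with medians of 12.97 against 8.21 and 8.3). Some material like LR in this library may contribute: its difference from replicate 2 correlated with that of LR from replicate 3 at 0.3 across rows, between the limits of 0.5 and 0.2 set beforehand, so this cannot be told apart from other causes. No biological explanation was tested.

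With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 7 pairwise comparisons 1 split, the real one, gave the highest count. The highest other count was 0, except for SS against treated cells grown alone, where it was 224 against 1598.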
